A study of Mus musculus with 6 samples.

How the data were processed

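Total RNA of mouse embryonic stem cells was measured on 6 Affymetrix Mouse430 version 2 arrays, 3 from cells transfected with an esiRNA against the long noncoding RNA Panct1 and 3 from cells transfected with an esiRNA against Luciferase. The deposited values are log2 signals, 1 per probe set and array, with 2 decimals. Per the submitters' processing notes, the software GCOS 1.4 and the RMA method were used to make them, and RMA corrects the background, quantile-normalises the arrays and summarises the probes of each set. Which arrays were normalised together, and the program that ran RMA, are not given in the sources used here. The deposited log2 values were used as they stand, with no further scaling in the main tests. Summaries of this kind pull small differences towards 0 for dim probe sets, and the number of arrays limits the precision of every value. Signals of different probe sets were not set against each other as abundances.

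The arrays were assigned to groups and replicate numbers from their titles. The labels do not state that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No pair of arrays was a copy: at most 3.20% of probe sets had the same value on any pair, counting equality at the 2 deposited decimals. Hybridisation dates were not used here, and no array, probe set or sample was left out for its values.

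The table held 45101 probe sets, of which 64 Affymetrix control sets were left out of the tests, leaving 45037. Probe sets were named from a platform annotation table: 34945 had 1 gene symbol, 932 had several and 9160 had none listed there. The symbols of 34741 of the probe sets with 1 symbol were updated through their gene ID with a RefSeq gene table of assembly GRCm38.p6, which was used for names alone. For the tests per gene, the probe set with the highest mean over all 6 arrays was taken among those with exactly 1 symbol, which gave 18193 genes. No probe set and no reference entry was named as Panct1 or by the accession the labels give for it. Neither the targeted RNA nor its neighbouring genes could therefore be picked out for a test of their own.

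Differences between Panct1 knockdown and Luciferase control were fitted on the log2 scale with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0, R 4.3.3), with the group as the only term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets or over all genes, and the threshold was an adjusted p under 0.05. The script was tested on simulated data for this comparison with 18193 genes: it recovered 6% of 50 genes shifted by 0.3 on the log2 scale, 90% at 0.6, 96% at 1 and 100% at 2. As 200 genes were changed there, these shares are not those of data with more changed genes. It made 2 calls among the unchanged genes, and 0 calls where no gene was changed.

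Before the data were examined, 27 gene lists were written from textbook knowledge, with 580 genes, of which 526 were measured. Each list was tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with the correlation estimated from the data. Members were counted as risen or fallen over all genes tested and adjusted over the list alone. limma's fry asked whether the genes of a list move, on balance, one way, or change in either direction, without comparing them with other genes.

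The genes named in the text were chosen by a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold whose 3 knockdown arrays all lay on one side of the 3 control arrays. It always takes Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, B2m and Gapdh, and the 4 members of each list with the smallest p. Gapdh has no probe set with 1 symbol other than the control sets, whose values were tested among the 64 control sets. The rule named 129 genes, of which 114 passed the threshold. For 113 of these the arrays of the groups did not overlap, the exception being Asns. A further 59 genes are named outside the rule and were chosen after their values were seen, and the text says so where they appear.

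The alternatives, also chosen before the data were examined, were the replicate number as a block, median centring, a repeated quantile normalisation, an intensity trend with robust variance, removal of the dimmer part of the probe sets, array weights, leaving out each array, removal of cross-hybridising probe sets, other choices of probe set per gene, a 1.5-fold minimum and the other list tests. A further 4 gene lists were added after the first results were seen and are used only among the additional observations.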

Results

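The series measured how RNA levels in mouse embryonic stem cells change after depletion of Panct1, a long noncoding RNA. The cells were of the Oct4-Gip line, in which regulatory sequences of Oct4 drive a green fluorescent reporter and a drug resistance gene, and they were grown in serum with LIF, a cytokine that sustains self-renewal. They were transfected with esiRNA, a pool of short double-stranded RNAs cut by an enzyme from a longer one. The 3 Panct1 knockdown arrays and the 3 control arrays, given an esiRNA against Luciferase, a gene that mouse cells lack, were prepared 72 hours after transfection of 60000 cells with 800 ng of esiRNA. All values are log2 RMA signals, and each array's median lay between 6.07 and 6.09. Arrays of 1 group correlated at 0.997 to 0.998 across probe sets, and arrays of different groups at 0.991 to 0.993. No probe set is named as Panct1 in the probe table used here, so the depletion was not assessed and the labels were not checked through the target. Whether any of the 9160 probe sets with no gene listed reads Panct1 is not known.

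Efemp1, which encodes the matrix glycoprotein fibulin-3, rose from 4.07 ± 0.11 (SD, n = 3) in controls to 7.24 ± 0.19 in knockdown, a log2 difference of 3.17 (SE 0.10; limma adjusted p = 8.43e-07). Its control signal lay below the lower quartile of every array (4.65 to 4.70), so the size of this rise is measured against background. Tagln, the actin-binding transgelin of smooth muscle, rose 6.29-fold to 11.46 ± 0.10, and Krt19 and Krt8, keratins of simple epithelia, rose 5.29-fold and 4.87-fold. Igf2, the imprinted growth factor, rose 5.07-fold, and Dsp, the desmosome protein desmoplakin, rose by the same factor. The other largest rises were in Slc39a8, a zinc importer (log2 difference 2.64), Anxa3, an annexin (2.62), Tmcc3 (2.53), Gbp2, an interferon-inducible GTPase (2.27), Nrk (2.27) and Samd4 (2.25). Their adjusted p-values in limma lay between 8.43e-07 and 2.88e-04. For Igf2, Dsp, Tmcc3 and Samd4, 1 probe set each did not pass, at 0.23, -0.01, 0.31 and 0.15.

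Srgn, the core protein of secretory granule proteoglycan, fell the most, from 8.09 ± 0.08 (SD, n = 3) to 4.73 ± 0.20, and so fell by 3.36 on the log2 scale (SE 0.10; limma adjusted p = 8.43e-07). Edn2, an endothelin, fell by 2.04, and Inhbb, a subunit of activin B, fell by 1.99. Gbx2, a homeobox gene that LIF induces in these cells, fell by 2.00. Rpl39l, a paralogue of a ribosomal protein gene, fell by 1.88 from a high signal of 12.15 ± 0.12. The others among the 12 largest falls were Gm20767, which fell by 2.29, AF067061, which fell by 2.01, Enox1, which fell by 1.88, and Ttn, the giant muscle protein titin, which fell by 1.84. Efhd1 fell by 1.82, AI662270 was 3.47-fold lower, and Akr1b8, an aldo-keto reductase, fell by 1.76. Of 6 probe sets for Ttn, 2 passed the threshold as fallen and the highest differed by 0.08. The second probe sets of Inhbb and Enox1 did not pass, at -0.19 and -0.34.

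**Figure D1:**
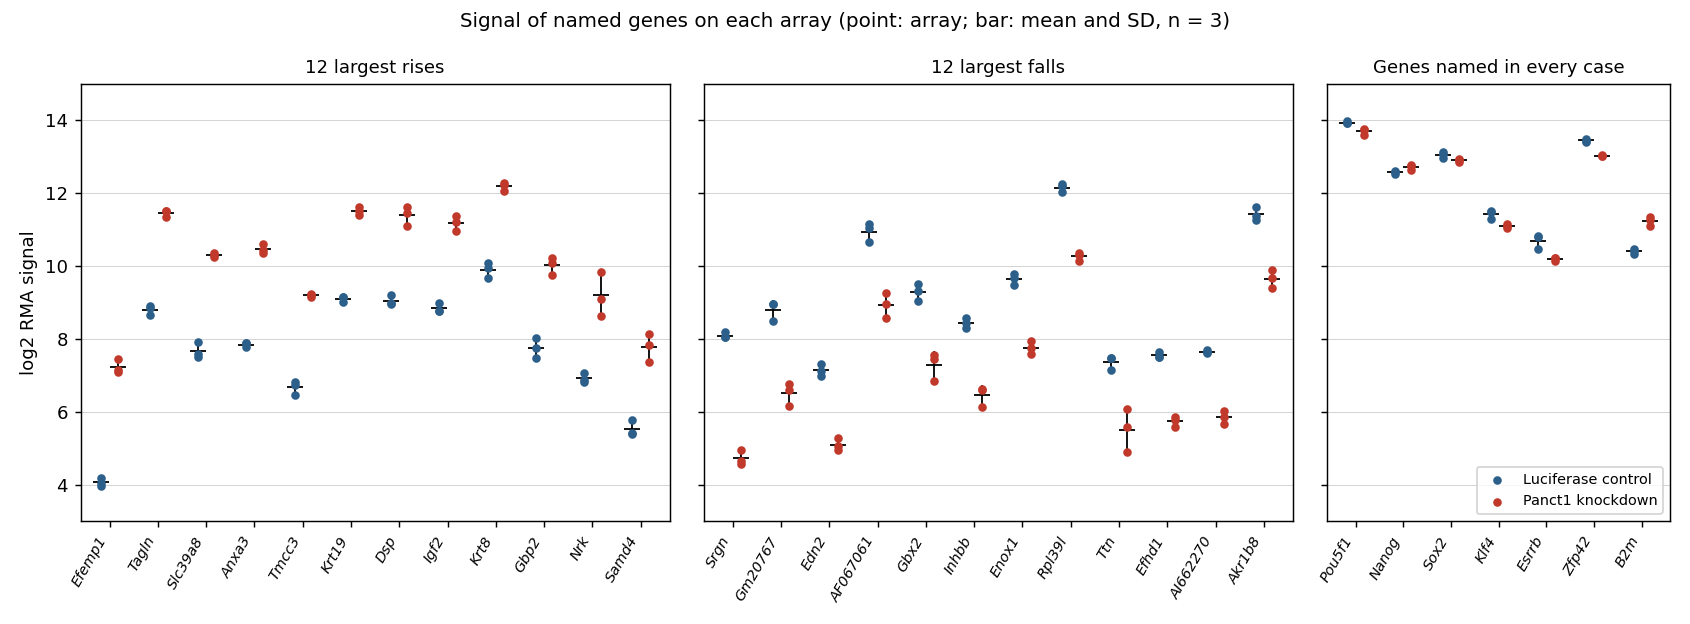
Log2 RMA signal (vertical axis) on each of the 3 Luciferase control arrays (blue) and 3 Panct1 knockdown arrays (red) for the 12 largest rises, the 12 largest falls and 7 genes named in every case; black bars give the mean and SD. For the largest rises and falls every knockdown point lies on 1 side of the control points, from Efemp1 (4.07 to 7.24) to Srgn (8.09 to 4.73), while Nanog (12.57 to 12.71) and Sox2 (13.05 to 12.91) did not pass the threshold.

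Over all genes, 4404 of 18193 (24.2%) changed, 2355 higher and 2049 lower in knockdown, by limma at an adjusted p under 0.05. Changes of at least 2-fold were found for 249 genes that rose and 93 that fell, and the smallest called difference was 0.19 on the log2 scale. Among 45037 probe sets, 6565 (14.6%) changed, 3520 higher and 3045 lower. The 3 arrays of each group did not overlap for 38.3% of genes and 30.4% of probe sets, against 10% by chance for 3 against 3 arrays. Of 9010 genes with several probe sets, 1144 had more than 1 past the threshold, and for 36 of these the probe sets went both ways. Without Luciferase control replicate 1 the count of probe sets was 4266, of which 1901 were lower. Of 85 named genes past the threshold with several probe sets, every probe set passed the same way for 33 and at least 1 did not pass for 52. Among the 52, none passed over all probe sets for Asns, Ttk, Cdh5 and, named after their values were seen, Sox3, Cebpb, Pfkl and Runx1. For 0 of the 85 a probe set passed the opposite way.

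Genes of trophectoderm, the outer epithelium of the blastocyst, rose as a group. Of 22 measured members, 14 rose and 0 fell; adjusted over the list alone, 15 rose and 0 fell. Krt7 rose 3.82-fold and Plet1, a surface protein of the placental lineage, rose 2.77-fold, beside Krt19 and Krt8. Cdx2, the transcription factor that sets up this lineage, rose 1.70-fold from 6.45 ± 0.07 (SD, n = 3) to 7.21 ± 0.13 (limma adjusted p = 2.17e-04), and Eomes rose by 0.49 on the log2 scale. Of members named after their values were seen, Krt18 (log2 difference 2.22), Tfap2c (1.00) and Gata3 (0.77) rose, while Elf5 differed by -0.19 and Hand1 by 0.10 without passing. The mean signal of Elf5 lay below the arrays' lower quartile in controls (4.50) and knockdown (4.31), so its lack of a call says little. The list's median difference was 0.63 (limma camera adjusted p = 1.36e-10), and it was the one list of 27 still past the threshold with an estimated correlation (adjusted p = 0.0434).

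Naive pluripotency genes were mostly lower: 19 of 31 measured members fell and 3 rose, and adjusted over the list alone 20 fell and 3 rose. Nr0b1, a nuclear receptor partner of Oct4, fell by 1.32 on the log2 scale (SE 0.07, n = 3 arrays per group, limma adjusted p = 6.45e-06). Manba fell by 1.11 and Fgf4, the growth factor made by the inner cell mass, fell by 0.92. Esrrb fell by 0.50, Zfp42, the marker Rex1, fell by 0.42, Klf2, named after its values were seen, fell by 0.55, Klf4 fell by 0.32 and Pou5f1, which encodes Oct4, fell by 0.24 from 13.93 ± 0.03 to 13.69 ± 0.10 (adjusted p = 0.0324). Nanog differed by 0.15 (adjusted p = 0.143) and Sox2 by -0.14 (adjusted p = 0.189) in limma, and neither passed. Nanog passed as risen with an intensity trend and robust variance (adjusted p = 0.0313). The 3 members that rose were Dppa3, a maternal factor of the early embryo, by 1.14, Gdf3 by 0.26 and, named after its values were seen, Tfcp2l1 by 0.43. The list passed in camera (adjusted p = 2.10e-05; adjusted p = 0.297 with an estimated correlation). The call for Pou5f1 was lost on leaving out any array but Panct1 knockdown replicate 3 (adjusted p from 0.0629 to 0.11), with the replicate number as a block (0.0860) and when adjusted over all probe sets (0.0571), with 0.00184 to 0.11 over the 12 settings run for it. The call for Klf4 was lost on leaving out knockdown replicate 2 or control replicate 1 or 3 (0.0551 to 0.0682; 0.00375 to 0.0682 over the 12 settings run for it, which keep its probe set).

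Genes of the 2-cell-like state, a rare state of these cultures that shares transcripts with the 2-cell embryo, were lower. Of 8 measured members 7 fell and 0 rose, over all genes and adjusted over the list alone. AF067061 fell by 2.01, Usp17la fell by 1.63, Tcstv3 fell by 1.29 and Arg2 fell by 0.95, with Tcstv3 ending at 3.70. That lies below the arrays' lower quartile, so the size of its fall is measured against background. Zfp352, named after its values were seen, differed by -0.11. Of the members not named by the rule, Tcstv1 and Ubtfl1, named after their values were seen, fell by 0.78 and fell by 0.35 with signals below the lower quartile in both groups. The call for Ubtfl1 was lost without Panct1 knockdown replicate 2 or 3 or Luciferase control replicate 2 or 3 (adjusted p from 0.0609 to 0.0755). The median difference was -0.86, the midpoint of Arg2 and Tcstv1 (limma camera adjusted p = 2.11e-05; adjusted p = 0.382 with an estimated correlation). Of the list's 22 genes, the others had no probe set of their own. Probe sets assigned to several genes with list members among them were chosen after their values were seen. The one for 6 genes, 4 of them on the list, fell by 2.15. The one for 7 genes fell by 2.03 and the one for 3 genes fell by 1.72, each with only 1 gene on the list.

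Among epiblast priming genes 7 of 22 rose and 5 fell, the same counts as adjusted over the list alone. Cldn6, a claudin of early epithelia, rose 2.49-fold and Wnt8a rose 2.04-fold, and Fgf5, the usual marker of primed epiblast, named after its values were seen, rose 2.71-fold. Foxd3 fell by 1.04, Fgf15 fell by 1.01, Dnmt3a fell by 0.81, and Otx2 and Sox3, named after their values were seen, both fell by 0.40. Of 31 primitive streak and mesoderm genes 9 rose, with Fgf8 at 2.08-fold and Mixl1 at 1.51-fold beside Cdx2 and Eomes, and 1 fell, Bmp4, named after its values were seen, which fell by 0.32; adjusted over the list alone the counts were 9 and 1. That list's median was -0.02 while its mean was 0.14 and camera's direction was up. Endoderm genes split 7 and 7 of 26 (8 rose and 7 fell adjusted over the list alone): Fst rose 2.00-fold and Amn 1.57-fold, while Lamc1 fell by 0.77 and Srgn, also on this list, fell as above. Of 31 neuroectoderm genes 7 fell and 3 rose (8 fell and 3 rose adjusted over the list alone). Pax6 fell by 0.97, Meis2 fell by 0.77 and Tubb3 fell by 0.41, while Map2 rose by 0.80 and, named after their values were seen, Nes by 0.64 and Fabp7 by 0.68. For Map2 1 of 4 probe sets passed, with the lowest at -0.03, and for Pax6 2 of 5, with the highest at 0.05. Germline genes fell in 7 and rose in 3 of 21, as adjusted over the list alone: Hormad1 fell by 1.44 to 4.36, also below the lower quartile, Stk31 fell by 1.29 and Mael fell by 0.74, while Rhox5, an X-linked homeobox gene, rose by 1.22 and, named after their values were seen, Ddx4 by 0.44 and Stra8 by 0.36. None of these 5 lists passed in limma's camera (adjusted p = 0.488, 0.181, 0.748, 0.0856 and 0.304 in this order). The neuroectoderm list passed without Luciferase control replicate 1 (adjusted p = 0.0411), without the dimmer part of the probe sets (0.0265) and with the mean of probe sets (0.0437). It ranged from 0.0265 to 0.443 over 14 camera settings. The streak and mesoderm list passed with the mean of probe sets (adjusted p = 0.0473; 0.0473 to 0.453 over 14 camera settings).

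**Figure D2:**
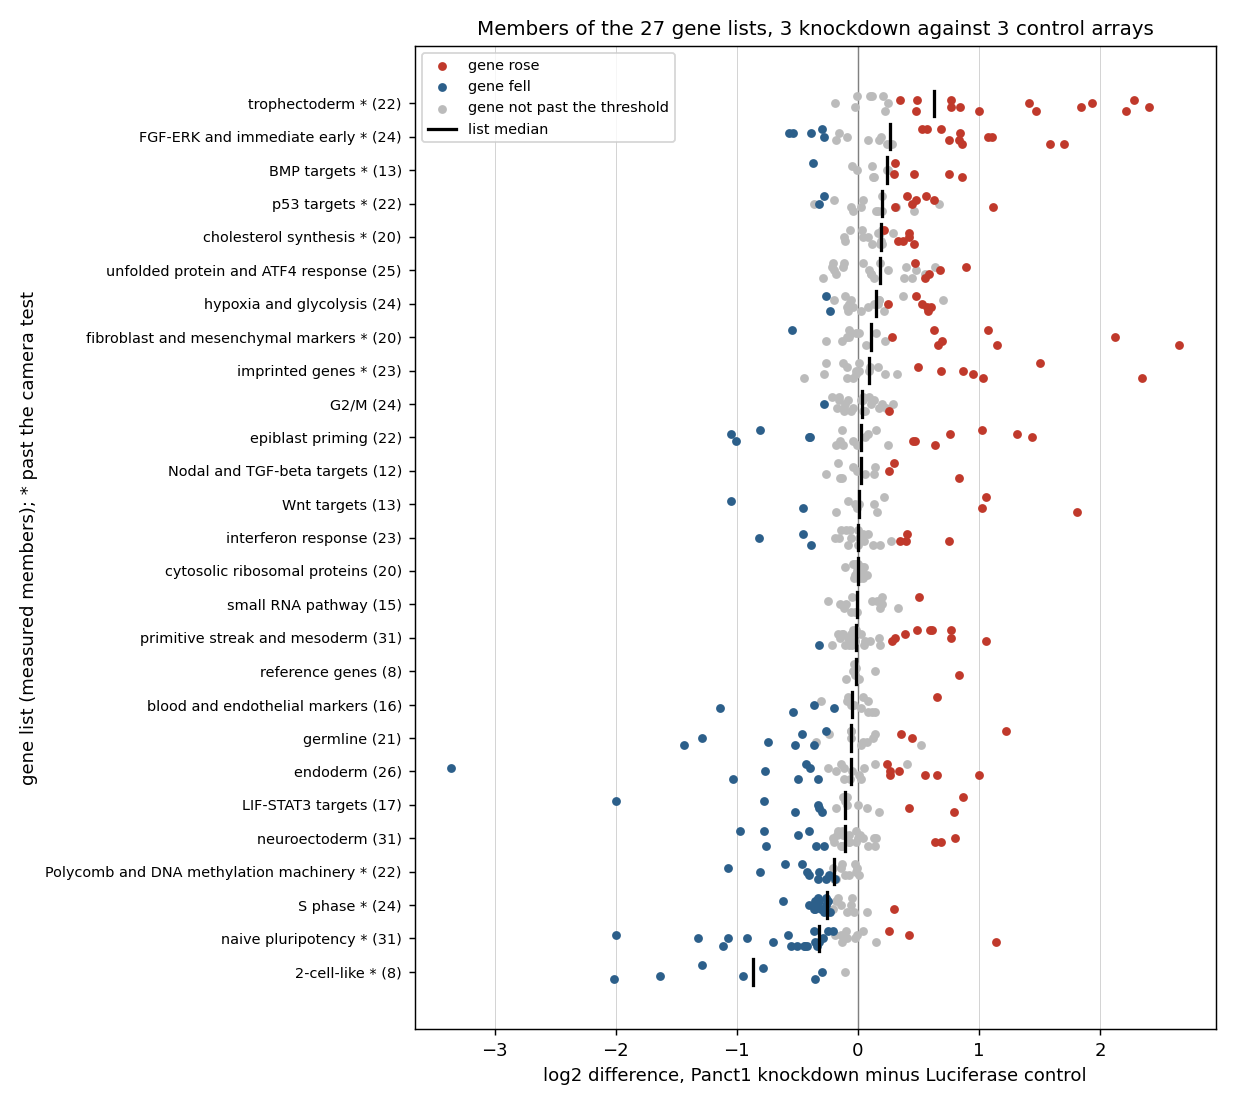
Log2 difference between Panct1 knockdown and Luciferase control (horizontal axis, n = 3 arrays per group) for every measured member of the 27 gene lists (vertical axis); points are genes, coloured where the gene rose or fell, and black bars are list medians. The trophectoderm list has the highest median, 0.63, and the 2-cell-like list the lowest, -0.86.

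Of 22 genes of the Polycomb and DNA methylation machinery 11 fell and 0 rose (13 and 0 adjusted over the list alone). Tet2, which oxidises methylcytosine, fell by 1.07, Dnmt3a, a de novo methyltransferase, fell by 0.81, its cofactor Dnmt3l fell by 0.60 and Kdm2b fell by 0.46, although 1 of 5 probe sets for Dnmt3a differed by 0.37. Camera called the list (limma adjusted p = 2.52e-05; adjusted p = 0.297 with an estimated correlation). Of 24 genes of S phase 14 fell and 1 rose (15 and 1 adjusted over the list alone): the replication factors Gins2, Mcm5 and Cdt1 fell by 0.62, by 0.35 and by 0.33, Uhrf1 fell by 0.40, and Ccne2, named after its values were seen, rose by 0.30. This list also passed (adjusted p = 3.95e-05; adjusted p = 0.398 with an estimated correlation). The G2/M list did not (adjusted p = 0.907): of 24 members Anln rose by 0.26 and Ttk fell by 0.28, Bub1 at -0.22 and Aurka at 0.18 did not pass, and 0 passed when adjusted over the list alone (7 at an unadjusted p under 0.05). Among 22 targets of p53, 7 rose and 2 fell (10 and 3 adjusted over the list alone). Perp, a membrane protein of desmosomal epithelia and cell death, rose 2.17-fold, the death gene Pmaip1 rose 1.48-fold, Phlda3 rose 1.37-fold and the cell cycle inhibitor Cdkn1a rose 1.33-fold, while Ei24 and Gtse1, named after their values were seen, fell by 0.32 and fell by 0.28. The p53 list passed (adjusted p = 0.0133; adjusted p = 0.598 with an estimated correlation).

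Imprinted genes rose in 7 of 23 and fell in 0; adjusted over the list alone 9 rose and 1 fell. Besides Igf2, the receptor adaptor Grb10 rose 2.84-fold from 10.55 ± 0.14 (SD, n = 3) to 12.06 ± 0.19, the zinc finger gene Plagl1 rose 2.05-fold and Nnat rose 1.94-fold. In limma's camera the list passed (adjusted p = 0.0126; adjusted p = 0.297 with an estimated correlation), but not without Luciferase control replicate 2 (adjusted p = 0.0615; 0.00446 to 0.297 over 14 camera settings).

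Among signalling genes, those of the FGF-ERK and immediate early list rose in 11 and fell in 5 of 24 (13 and 6 adjusted over the list alone). Ccn1, a matrix-associated early response gene, rose 3.01-fold, Klf6 rose 2.16-fold and the phosphatases Dusp1 and Dusp4 rose 2.10-fold and 1.79-fold. Of genes named after their values were seen, Fos rose by 1.70, while Myc fell by 0.57, Ier2 fell by 0.53, Spry4 fell by 0.39, Etv5 fell by 0.29 and Spry2 fell by 0.28. The list passed in camera (limma adjusted p = 0.00453; adjusted p = 0.382 with an estimated correlation). BMP targets rose in 5 and fell in 1 of 13, over all genes and adjusted over the list alone: the inhibitory Smad6 rose by 0.86, Dusp9 by 0.75, Id3 by 0.46, Smad7 by 0.30 and, named after its values were seen, Msx2 by 0.31, and Id1 fell by 0.37. That list passed (adjusted p = 0.0156; adjusted p = 0.453 with an estimated correlation), but not without the dimmer part of the probe sets (adjusted p = 0.0527; 0.00565 to 0.453 over 14 camera settings). Wnt targets rose in 3 of 13, Sp5 3.51-fold, Fgf8 and Wnt8a, and fell in 2, Notum, which fell by 1.04, and Ccnd1, named after its values were seen, which fell by 0.45, with the same counts adjusted over the list alone (camera adjusted p = 0.445). Of 12 Nodal and TGF-beta targets 3 rose, Ccn2 by 0.84, Smad7 and Gdf3, and 0 fell (3 and 1 adjusted over the list alone, with Tgfbi at -0.27 not past the threshold over all genes; camera adjusted p = 0.455). Of 17 LIF-STAT3 targets 6 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.304): Bcl3 fell by 0.52, and Nfkbiz rose by 0.87 and the kinase gene Pim1 by 0.80, beside Gbx2 and Tfcp2l1.

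Cholesterol synthesis genes rose in 6 of 20 and fell in 0 (9 and 0 adjusted over the list alone). Sc5d rose by 0.47, Srebf2, which encodes the pathway's transcription factor, by 0.42, Stard4 by 0.42 and Sqle, squalene epoxidase, by 0.38 (limma camera adjusted p = 0.00276; adjusted p = 0.448 with an estimated correlation). Of 24 hypoxia and glycolysis genes 6 rose, among them the glucose transporters Slc2a1 by 0.58 and Slc2a3 by 0.57, Tpi1 by 0.53 and Hk1 by 0.48, and 2 fell, Pdk1, which fell by 0.27, and Pfkl, which fell by 0.23, both named after their values were seen. Adjusted over the list alone the counts were 6 and 2 (camera adjusted p = 0.0661, but 0.021 without Panct1 knockdown replicate 1 and 0.0475 with the replicate number as a block, with 0.021 to 0.453 over 14 camera settings). All 4 probe sets for Slc2a3 passed as risen, by 0.57 to 1.48. The value given above is the lowest, from the brightest set, whose mean signal was 14.09 in knockdown. In the unfolded protein and ATF4 list 5 of 25 rose and 0 fell (2 and 0 adjusted over the list alone): Ddit4 by 0.90, Atf3 by 0.68, Asns by 0.59, Phgdh by 0.47 and Cebpb, named after its values were seen, by 0.56. Camera did not call it (limma adjusted p = 0.0677), but did without Panct1 knockdown replicate 1 (adjusted p = 4.47e-05), without Luciferase control replicate 1 (0.0388), with the replicate number as a block (0.0333) and with the mean of probe sets (0.0437). It ranged from 4.47e-05 to 0.697 over 14 camera settings. Interferon response genes rose in 4 and fell in 3 of 23 (6 and 3 adjusted over the list alone), with a median of 0.00 (camera adjusted p = 0.873). The RNA sensor Ifih1 rose by 0.75, Irf1 by 0.40 and, named after their values were seen, Oasl2 by 0.41 and Usp18 by 0.35, while the RNA sensor Ddx58 fell by 0.82, Ifitm3 fell by 0.39 and Irf9, named after its values were seen, fell by 0.45. In the small RNA pathway 1 of 15 genes rose, Prkra by 0.51, and 0 fell, as adjusted over the list alone (camera adjusted p = 0.488), with Ago2 at 0.33, Dgcr8 at 0.20 and Lin28b at -0.24 not past the threshold. Of 4 probe sets for Ago2, 1 rose by 0.44 (adjusted p = 0.0256 over all probe sets). The mean signal of Lin28b lay below the arrays' lower quartile in both groups. Of 20 cytosolic ribosomal protein genes 0 passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.946), and Rps6 differed by -0.10, Rps16 by 0.08, and Rpl19 and Rpl10a by 0.05. The probe set for Rps16 also had a mean signal below the lower quartile in both groups.

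Of 20 fibroblast and mesenchymal markers 8 rose and 1 fell (8 and 2 adjusted over the list alone). Thbs1, the matrix protein thrombospondin, rose 4.35-fold, Acta2, smooth muscle actin, rose 2.22-fold and Col5a2 rose 1.58-fold beside Tagln. For Acta2 1 of 3 probe sets passed and for Col5a2 1 of 2, with the lowest at -0.02 and 0.23. Named after their values were seen, Vim, the mesenchymal filament protein, fell by 0.55, and Col1a2 and Fn1 differed by 0.01 and -0.07. The list passed in limma's camera (adjusted p = 0.0126; adjusted p = 0.297 with an estimated correlation), but not without the dimmer part of the probe sets (adjusted p = 0.0679; 0.00556 to 0.297 over 14 camera settings). Blood and endothelial markers fell in 4 and rose in 1 of 16, by either adjustment (camera adjusted p = 0.447): Cd68 fell by 1.14, Gata1 fell by 0.53, Cdh5 fell by 0.36, Runx1, named after its values were seen, fell by 0.20, and Tek rose by 0.66.

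Of 8 measured reference genes 1 rose and 0 fell, over all genes and adjusted over the list alone. It was B2m, the light chain of MHC class I and a reference for the study's PCR measurements per the labels, which rose 1.78-fold from 10.40 ± 0.08 (SD, n = 3) to 11.23 ± 0.12 (limma adjusted p = 1.38e-04). Ywhaz differed by 0.14, Tbp by -0.10 and Sdha by -0.03. The 7 probe sets for Ywhaz lay at 0.11 to 0.32, and 1 of them passed as risen (adjusted p = 0.0104 over all probe sets). Gapdh, the other reference in the labels, differed by 0.10, 0.09 and 0.08 on its 3 control probe sets (adjusted p = 0.488 over the 64 control sets), none of which passed. The list's median of -0.02 and mean of 0.10 differ in sign, with camera's direction up (adjusted p = 0.578). Medians and means also differed in sign or were 0 for the interferon, small RNA and ribosomal lists, whose means were 0.01, 0.06 and 0.00.

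Of the 27 lists, 11 passed in limma's camera, 7 of them higher and 4 lower in knockdown. With an estimated correlation 1 passed, in fry's test of movement one way 16, and in fry's test of change in either direction 25. Camera with an estimated correlation was stricter even where the estimate was low. For the trophectoderm list it was -0.0141, below the preset 0.01, and camera's unadjusted p went from 5.04e-12 to 0.00161. For the fibroblast list it was -0.0123, and camera's unadjusted p went from 0.00377 to 0.0342. A call lost there is thus not always a sign of correlation among the members. Among lists that lost the call, the estimate ran from -0.0123 for the fibroblast list to 0.568 for the 2-cell-like list. It was 0.291 for the p53 list and 0.229 for the S phase list, so correlation may account for such losses. The test of movement one way did not call the p53 list (adjusted p = 0.0534), and called 6 lists that camera did not: streak and mesoderm (0.0304), endoderm (0.0412), neuroectoderm (0.0200), hypoxia and glycolysis (0.0229), blood and endothelial (0.00982) and reference genes (0.0304). Endoderm members split 7 risen and 7 fallen, with Srgn at -3.36, and of the reference genes B2m alone passed. The test was not repeated without Srgn or B2m. Besides Pou5f1 and Klf4, the calls of Anln, Asns, Cdh5, Gdf3, Phgdh, Smad7, Stard4 and Ttk ended in at least 1 other setting. So did those of 16 genes named after their values were seen: Bmp4, Ccne2, Cebpb, Ei24, Etv5, Fabp7, Gtse1, Msx2, Pdk1, Pfkl, Runx1, Sox3, Spry4, Stra8, Ubtfl1 and Usp18. Of genes not past the threshold, Bub1, Aurka, Ago2 and, named after their values were seen, Cdh1 and Psmb10, like Nanog, passed with an intensity trend and robust variance (adjusted p from 0.0155 to 0.0498), Bub1, Aurka and Psmb10 also without the dimmer part of the probe sets, and Aurka, Ago2 and Cdh1 also with array weights. Tgfbi passed without Panct1 knockdown replicate 1 (adjusted p = 0.0420), without the dimmer part (0.0407) and with a repeated quantile normalisation (0.0344), and Dgcr8 without Luciferase control replicate 3 (0.0494).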

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

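All alternatives reported here were chosen before the data were examined, and 0 were added later. Genes named by the rule were followed over at most 12 settings, which leave out the other choices of probe set and the removal of cross-hybridising sets. Over these the direction of each was kept: 1482 comparisons gave the same call, 44 lost it and 12 gained it. For the genes named after their values were seen, over the same settings, 609 gave the same call, 83 lost it and 4 gained it, again with 0 reversals. Of the list comparisons 365 were the same, 14 lost the call, 16 gained it and 9 reversed, all for lists not called in the main test. Counts stayed within 1.5 times the main value in 92 comparisons and moved in 8.

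The replicate numbers did not pair the arrays: same-numbered arrays had correlations of -0.158, -0.302 and -0.150 between their deviations from the group means, and 0 of 3 correlated best with its own number. With the replicate number as a block, probe sets fallen were 1965, and 3496 genes were called, 3448 of them among the main 4404. Leaving out 1 array gave 4266 to 5574 probe sets changed, 1901 to 2501 probe sets fallen and 3133 to 3986 genes changed. The lowest of these counts came without Luciferase control replicate 1, which leaves fewer samples. A 1.5-fold minimum left 1227 genes changed, 837 risen and 390 fallen, by its own construction. Gene lists past the threshold were 1 with an estimated correlation and 25 with fry in either direction. Without the dimmer part of the probe sets the mean of the interferon list was -0.0731 and that of the ribosomal list -0.00368. On leaving out 1 array, list means ranged from -0.0113 to 0.0142 for ribosomal, -0.00935 to 0.0320 for interferon, -0.0231 to 0.0356 for G2/M and -0.174 to -0.114 for endoderm genes, with camera's direction turning at least once for each. The cause was not tested. Without the dimmer part 4437 genes were called, 3893 of them among the main 4404. Among calls shared with the main test, 1 had the opposite direction with the mean of probe sets and 4 with the choice by suffix.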

Other observations

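The 4 gene lists of this part were written after the first results were seen, from genes whose values had not been looked at, and the tests on them were set down before their values were computed. The members of these lists named here were chosen after their values were seen, and so was the look at the poly-A spikes. Genes of the actin cytoskeleton, many of them targets of the transcription factor SRF, were higher in Panct1 knockdown: 13 of 15 measured members rose and 0 fell. Tropomyosin Tpm1 rose 2.93-fold from 10.51 ± 0.01 (SD, n = 3) to 12.07 ± 0.07, the myosin light chain Myl9 rose 3.11-fold and the nonmuscle myosin heavy chain Myh9 rose 2.05-fold (limma adjusted p = 2.81e-06, 2.28e-05 and 1.83e-05), while Actn1 at 0.16 and Actg2 at 0.14 did not pass. The mean signal of Actg2 lay below the arrays' lower quartile in both groups. Genes of desmosomes and epithelial junctions rose in 12 and fell in 0 of 17, with the claudins Cldn7 at 3.41-fold and Cldn4 at 2.36-fold and desmoglein Dsg2 at 2.40-fold, whereas Cdh1, E-cadherin, at 0.19 and Jup at -0.10 did not pass.

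Genes of MHC class I presentation also rose, in 9 of 11, with 0 falls. The immunoproteasome subunit Psmb8 rose 2.63-fold, the heavy chains H2-K1 and H2-D1 rose 1.57-fold and 1.52-fold and the peptide transporter Tap1 rose 1.42-fold (limma adjusted p = 1.58e-05, 6.04e-04, 6.82e-04 and 0.00143), while Psmb10 at -0.17 and Nlrc5 at 0.10 did not pass.

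For the rise of Krt8, Krt19 and Tagln, raised expression of actin cytoskeleton genes as a group is one hypothesis: the list had a median log2 difference of 0.867 (limma camera adjusted p = 4.13e-14; adjusted p = 0.0178 with an estimated correlation). An epithelial junction programme is another candidate explanation, with a median of 0.413 (adjusted p = 6.92e-09; adjusted p = 0.0178 with an estimated correlation). Raised YAP-TEAD activity stays open. Of 17 targets 8 rose, Amotl1 by 1.52 and Ptpn14 by 1.31, and Dock5 fell by 0.41, while Ankrd1 differed by -0.17. The median of 0.210 lies between the bounds set beforehand (camera adjusted p = 3.11e-04, and 0.0178 with an estimated correlation). Ccn1 and Ccn2, whose rises are given above, had already been seen and so were not on that list. Admixed fibroblasts as a source of the contractile and matrix transcripts cannot be told apart from a change in the cells themselves, because 9 abundant stromal genes had a median difference of 0.153, under the bound of 0.25 set to argue against them, but with a bootstrap interval from -0.0867 to 0.63 that crosses it. Of these genes 3 rose, and the mean signals of the 9 in knockdown were 4.27 to 7.35. Off-target effects of the single esiRNA and cell density were not tested.

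For the rise of B2m and Gbp2, raised MHC class I presentation as a group had a median difference of 0.603 (limma camera adjusted p = 4.23e-07; adjusted p = 0.0178 with an estimated correlation). As B2m is itself a part of MHC class I, this widens the description of its rise and gives no cause. A general interferon response to double-stranded RNA that was stronger in knockdown would lift the interferon list by 0.5 or more. The list's median was 0, with a bootstrap interval from -0.0967 to 0.123 and 17.4% of members risen, which argues against a rise of that size across the list. No array shows how far this list can rise in these cells, so a weaker response is not excluded. Some members were dim, with Usp18 at 4.62 and Oasl2 at 4.73 in controls, near the arrays' lower quartile. Both groups received 800 ng of esiRNA, so a response shared by both would cancel and cannot be seen here. A narrower response, limited to some genes such as Gbp2 and the presentation genes, may remain and was not tested.

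The number of probe sets changed, 6565, was met by 1 of the 10 splits of the 6 arrays into 3 and 3, the real one. The highest count in any other split was 0. Every other split mixes the groups on both sides, so the group difference widens the spread and holds that count down. The 10 splits cannot give a share under 0.05, the smallest being 0.1, and so do not settle the part of chance. RNA degradation or a labelling difference stays open: the 3' minus 5' signal shifted by 0.01 for Gapdh and 0.0033 for beta-actin, which reads the ends of 2 RNAs and not the yield of labelling, and it shifted by 0.147 for Tfrc and by -0.243 for Pcx, whose arrays did not overlap. Of 24 poly-A spike probe sets, which read RNAs made to be added before labelling, 23 were higher in knockdown, with a median of 0.275 and the dap sets at 0.44 to 0.55; 0 passed in limma among the control sets (2 at an unadjusted p under 0.05), and for 1 the arrays did not overlap, against 10% by chance. For a hybridisation difference, the 18 probe sets of the spiked BioB, BioC, BioD and Cre RNAs had a median difference of 0.0583. Their largest was 0.17, below the smallest difference of 0.213 among changed probe sets, although 17 were higher in knockdown and only 1 was lower. These few RNAs, read after normalisation, argue against a large shift of their own signals. They cannot exclude a hybridisation difference for other probe sets. Whether the groups were grown, labelled or hybridised on different days is not in the labels, so such a batch cannot be told apart from the knockdown.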
